A study of Mus musculus with 4 samples.

How the data were processed

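Gene expression was measured in the livers of male C57BL/6 mice, the most widely used inbred laboratory strain, that were given a diet rich in fat and sucrose (HFHS) for 0, 5, 10 or 15 weeks. The mice were 5 weeks old when the diet began, so the samples come from animals aged 5, 10, 15 and 20 weeks. The series has 4 arrays, with 1 array per time point. The series text speaks of 4 mice per time point and does not say whether the RNA on an array came from 1 of them or from a pool. Time on the diet and age moved together, and mice of the same age on a control diet are not analysed here, so no comparison separates the diet from growth and ageing.

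Per the labels' protocols, total RNA was taken from frozen liver, checked for quality on a Bioanalyzer, amplified from a low input and labelled with Cy3, a green fluorescent dye. Per the file headers, the 4 samples were hybridised to 1-colour Agilent arrays of 1 design and read with Agilent Feature Extraction version 10.7.3.1, and the 4 scans carry the same scan time, so no scan batch divides the time points. Each scanner file gives, per the file headers, a processed signal for every spot, which is a fluorescence intensity on a linear scale from which the software had subtracted background and spatial trends. The scanner files also hold, per the file headers, the raw mean intensity and the local background intensity of each spot, and marks for spots well above background, uneven spots and saturated spots. The authors also deposited a value table of intensity on a linear scale. Dividing the processed signal of each spot by the deposited table gave 1 constant per array, equal to that array's median over non-control spots, so the scale is linear, genes are not centred and the median of every column is 1.

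All values given here were computed from the scanner files. The main values were the log2 of the processed signal minus the array's 75th percentile over non-control spots. Control spots and spots marked as uneven or as outliers were left out, spots of the same probe were averaged, and each gene was represented by the probe with the highest mean over the 4 arrays. A gene counted as measured in a comparison when its probe was well above background on both arrays, and it was called higher or lower when the arrays differed at least 2-fold. For a gene above background on 1 of both arrays, a bound was computed as the brighter value over the larger of the dim probe's own value and a floor, and it is written as at least N-fold. The floor was the lowest value on that array among probes well above background, with the spots of a probe averaged and a repeated probe counted as above background when most of its spots were. On the log2 scale it was −3.59, −3.44, −3.58 and −4.11 at 0, 5, 10 and 15 weeks, where the lowest single spot well above background gives −3.51, −3.44, −3.39 and −4.04 and so somewhat smaller bounds. With 1 array per time point there is no replicate check on any difference between times, and no test was made of these differences or of a trend over the 4 arrays. The number of arrays limits the precision of every value.

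Probes were named through the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of 55681 probes, 27509 were matched by accession, 3549 by symbol and 404 by an older symbol, and 24219 kept the name in the scanner file. Positions of probes are those in the scanner files, in build mm9. Where a gene had several probes these could disagree: of 539 such genes with a probe at least 2-fold different between 15 and 0 weeks, 82 had probes of opposite direction. Genes of families with near-identical members, such as Saa1 and Saa2, the Cyp2b, Cyp2c and Cyp3a families, the major urinary proteins and the globins, can share signal between probes, so values of single members are uncertain.

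The 4 arrays had 44.9%, 44.5%, 44.6% and 48.3% of non-control spots well above background at 0, 5, 10 and 15 weeks, and 18110, 17934, 18074 and 19287 genes above background. No spot was saturated. The median SD over the 10 spots of a repeated probe was 0.0629, 0.0743, 0.0629 and 0.0659 on the log2 scale, which covers error between spots of an array and not between animals. After scaling, the median measured gene differed from 0 weeks by −0.02 at 5 weeks, −0.01 at 10 weeks and −0.25 at 15 weeks. With the array median in its place these medians were −0.08 at 5 weeks and −0.11 at 10 weeks. At 15 weeks the median depended on the scaling and was −0.18 with the array median, −0.05 with the 75th percentile of detected probes, −0.08 with quantile normalization, −0.06 with normexp and 0.26 with spike-in scaling. Medians of gene lists are therefore given relative to the median of all measured genes. Folds of single genes are given as scaled, and against the median measured gene the log2 differences of single genes at 15 weeks lie 0.25 above those printed.

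Before the data were examined, the groups, the comparisons, the 2-fold threshold, the gene lists, the rule for named genes and most alternatives were fixed. The comparisons were 5, 10 and 15 weeks against 0 weeks, 10 against 5 weeks and 15 against 10 weeks, the genes different from 0 weeks in the same direction at all 3 times, and the genes ordered in time. The 41 gene lists covered lipid and glucose metabolism, liver functions and zones, stress, inflammation, matrix, cell cycle, the clock and markers of the cell types a liver sample can hold. They held 804 entries for 754 genes, of which 9 were not found on the array and 7 were found through an older symbol. The lists overlap in places, and 1 duplicate entry, an older name of Ciart, was removed from the night-peaking clock list. For each list, the median log2 difference of its measured members was set among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes these arrays and is no test, since genes are not replicates. Lists with fewer than 5 measured members were given no percentile.

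The rule for named genes took, for each time against 0 weeks, the 10 genes with the largest and the 10 with the smallest log2 difference among genes with an official symbol measured on both arrays and outside the lowest-expressed part of the genes (upper 2/3 kept), the 10 higher and 10 lower genes with the largest minimum difference among those at least 2-fold different in the same direction at all 3 times, up to 4 members of each list with the largest difference at the time described, and a short list of fixed names. Predicted and clone-named transcripts were counted and not named, and a few genes that the rule takes are not reported here. List members measured on only 1 of both arrays, and any others outside the rule, are said to be chosen after their values were seen where they are named.

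Alternatives were scaling by the array median, by the 75th percentile of probes detected on all 4 arrays or by quantile normalization, normexp background correction (offset 50) with quantile normalization, the deposited value table, no background filter, a filter on all 4 arrays, the mean of a gene's probes, keeping outlier spots, thresholds of 1.5-fold and 3-fold, the mean of a list in place of its median, and unmatched random lists. After the data were seen, spike-in scaling, leaving out probes with a run of at least 5 TG or AC units, leaving out spots with at least 5 bright neighbours and keeping the duplicate clock entry were added. A neighbour was bright when it lay at least 2-fold above the other arrays, among spots up to 4 rows and 2 columns away.

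The steps were tested on simulated data drawn around the mean values of 16684 genes, of which 200 were changed between 15 and 0 weeks, with log2 noise of SD 0.1. All genes changed 2.5-fold, 4-fold or 8-fold were recovered at the 2-fold threshold (100%), genes changed 1.5-fold were not (0%), and 0 unchanged genes passed. With so little noise this outcome was fixed in advance. The real log2 differences from 0 weeks had an SD of 0.442, 0.466 and 0.683 at 5, 10 and 15 weeks. Among 200 unchanged lists in the simulated comparison of 5 with 0 weeks, 3.5% lay outside the middle 95% of random lists. These lists held randomly drawn genes with independent noise. The simulation thus checks the computation and gives no rate of false calls in these data. A planted block of bright spots on the 5-week array was marked in full (100%), with 0 spots marked on the other arrays. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.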

Results

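Liver RNA from male C57BL/6 mice was measured on 4 arrays, 1 for each of 0, 5, 10 and 15 weeks on a diet rich in fat and sucrose. The mice started the diet at 5 weeks of age and were 5, 10, 15 and 20 weeks old at sampling. Signals well above background were read from 44.9%, 44.5%, 44.6% and 48.3% of the non-control spots, which gave 18110, 17934, 18074 and 19287 genes above background. The 75th percentile of the processed signal was 208.2, 207.7, 193.7 and 271.6.

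The comparisons ask which liver genes differed with the length of feeding. Each rests on 1 array per time point and so has no replicate check, and age moved together with time on the diet. Folds of single genes are as scaled to the 75th percentile of each array. Medians of gene lists are relative to the median of all measured genes, which stood at −0.25 on the log2 scale at 15 weeks, and are called outside the random range where they lie outside the middle 95% of the medians of 10000 matched random lists. Of the 41 lists, 26, 27 and 32 lay outside at 5, 10 and 15 weeks against 0 weeks. Between 5 and 10 weeks 27 did, and between 10 and 15 weeks 28, where 2.05 are expected of random lists. Lying outside was thus usual and does not by itself set a list apart.

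At 5 weeks against 0 weeks, the genes furthest above included Hsd3b5, a male-biased hydroxysteroid dehydrogenase (19.3-fold higher), Cyp7b1, a male-biased oxysterol hydroxylase (13.8-fold higher), Cfd, the adipocyte protease adipsin (18.5-fold higher), Saa2, an acute phase apolipoprotein (8.62-fold higher), and Fabp5, a fatty acid carrier of macrophages and adipocytes (7.17-fold higher). Those furthest below included 3 members of the Cyp3a family of drug-metabolising cytochromes, Cyp3a41b (15.6-fold lower), Cyp3a16 (14.3-fold lower) and Cyp3a11 (11.2-fold lower), whose probes can share signal. Hamp2, a hepcidin gene (9.22-fold lower), Ptgds, a prostaglandin D synthase (7.24-fold lower), Lgals2, a galectin (6.29-fold lower), Vsig2 (5.53-fold lower) and the cytochrome Cyp2s1 (5.43-fold lower) were also lower. Of 17093 genes measured on both arrays, 394 were at least 2-fold higher and 267 at least 2-fold lower. The share of higher genes was 59.6%, or 51.7% with scaling to the array median.

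Genes of cholesterol synthesis stood above the median gene as a group at 5 weeks. Of 25 measured members, 6 were at least 2-fold higher, 0 lower and 19 within 2-fold, with a relative median of 0.42, outside the random range. They included Sqle, the squalene epoxidase (5.73-fold higher), Cyp51, the lanosterol demethylase (3.88-fold higher), and Idi1, of the isoprenoid part of the pathway (2.74-fold higher). Of 21 genes of fatty acid synthesis, 2 were higher and 19 within 2-fold (relative median 0.13, outside the random range). The desaturase Fads2 was 2.15-fold higher. Fasn, the fatty acid synthase, was within 2-fold at −0.04 on the log2 scale. With random lists not matched on expression, the fatty acid synthesis list lay within the range (percentile 96.97).

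Markers of macrophages, interferon-stimulated genes and chemokines stood above the median gene as groups at 5 weeks, with most members within 2-fold. Of 22 Kupffer cell and macrophage markers, 5 were at least 2-fold higher and 17 within 2-fold, with a relative median of 0.89, and among them were the protease Ctss (2.51-fold higher), the lysozyme Lyz2 (2.47-fold higher), the pore protein Mpeg1 (2.35-fold higher) and the lysosomal protein Cd68 (2.31-fold higher). Of 13 markers of lipid-associated and recruited macrophages, 5 were higher and 8 within 2-fold (0.88), led by Fabp5, the chemokine receptor Cx3cr1 (4.51-fold higher), the lipid receptor Trem2 (3.07-fold higher) and Clec7a (2.27-fold higher). Of 24 interferon-stimulated genes, 8 were higher and 16 within 2-fold (0.85), with Gbp3, a guanylate-binding protein, 2.84-fold higher and Oas1a, an oligoadenylate synthase, 2.36-fold higher. Of 13 cytokines and chemokines, 2 were higher and 11 within 2-fold (0.45), namely Cxcl1, a neutrophil chemokine (4.92-fold higher), and Ccl2, a monocyte chemokine (2.33-fold higher), whose spots had up to 5 of 44 neighbours bright on this array. All 4 medians lay outside the random range. Sinusoidal endothelial markers stood at 0.27 with 0 of 17 at least 2-fold different, and hepatocyte markers at −0.14 with 0 of 17, both outside the random range too (hepatocyte markers within it, at percentile 3.05, with unmatched random lists).

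Several male-biased liver genes were higher and several female-biased genes lower at 5 weeks than at 0 weeks, when the mice were 5 weeks old. Of 15 measured male-biased genes, 7 were at least 2-fold higher and 8 within 2-fold, or 8 higher against the median gene (relative median 1.01), including Elovl3, a fatty acid elongase (5.13-fold higher), and Susd4 (4.79-fold higher). Of 9 female-biased genes, 4 were lower and 5 within 2-fold (−0.77), including Slco1a4, an organic anion transporter (5.15-fold lower), and Cyp39a1, an oxysterol hydroxylase (4.90-fold lower). Among 12 drug-metabolising cytochromes 4 were lower and 8 within 2-fold (−0.78). These 3 medians lay outside the random range, and the lists share members such as Cyp3a16. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 1.63 on the log2 scale, while the 20 measured bile acid genes together lay within the random range (−0.11, 2 higher, 1 lower, 17 within 2-fold). This list lay outside the range, on the lower side, with quantile normalization (percentile 2.28), no background filter (2.44) and the mean of each gene's probes (0.13). It stood above 0, within the range, with locally bright spots left out (0.02) and by the mean (0.08).

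Some liver functions stood below the median gene at 5 weeks. Amino acid and urea cycle enzymes had a relative median of −0.41 with 1 of 22 at least 2-fold lower and 21 within 2-fold, namely the histidine ammonia-lyase Hal (2.33-fold lower). Periportal hepatocyte genes stood at −0.52, with 4 of 16 lower, 0 higher and 12 within 2-fold, led by Etnppl (3.55-fold lower) and Sdsl (3.30-fold lower). Genes of oxidative stress and NRF2 stood at −0.40 with 3 of 20 lower and 17 within 2-fold, led by the glutathione transferases Gsta2 (3.59-fold lower) and Gstm3 (2.12-fold lower). Bile duct cell markers stood at −0.41, with 1 of 12 higher, 3 lower and 8 within 2-fold, and the keratin Krt19 was 5.07-fold lower. All 4 medians lay outside the random range, while the mean of the bile duct list, −0.25, lay just within it. The 1 higher bile duct marker was the keratin Krt7 (16.6-fold higher), whose spot had 5 of 44 neighbours bright on this array.

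Adipocyte markers had a relative median of 0.71, with 4 of 8 at least 2-fold higher and 4 within 2-fold, and lay outside the random range beside the lipid genes. Besides Cfd they were the carbonic anhydrase Car3 (2.81-fold higher), the droplet protein Cidec (2.26-fold higher) and the fatty acid carrier Fabp4 (2.10-fold higher). Car3 was already bright at 0 weeks, with a scaled log2 signal of 6.35 against −0.03 for Cfd. Genes of PPAR-gamma and lipid uptake, which share Cidec and Fabp4, had 3 of 15 higher, 1 lower and 11 within 2-fold and lay within the random range (−0.03). Of 21 lipid droplet genes, 4 were higher and 17 within 2-fold (0.12, outside the random range), with G0s2, an inhibitor of lipolysis, 2.64-fold higher. Fatty acid oxidation genes stood at 0.11, with 2 of 30 higher and 28 within 2-fold, also outside the random range. Neither the droplet list nor the oxidation list lay outside with unmatched random lists (percentiles 96.85 and 97.46). The 2 higher oxidation genes were Fgf21, a hormone secreted by the liver (5.37-fold higher), and the kinase Pdk4 (2.60-fold higher), whose spot had 21 of 44 neighbours bright on the 5-week array.

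Several of the largest values at 5 weeks came from spots with bright neighbours. B3galnt1 (17.8-fold lower) and Tfdp2 (13.5-fold lower) had 27 and 23 of 44 neighbours bright on the 0-week array, and the other probe of Tfdp2 differed by −0.32 on the log2 scale. On the 5-week array Slc25a48 (17.2-fold higher) had 23 bright neighbours, Prickle3 (14.7-fold higher) 21, Tmem159 (18.8-fold higher) 14 and Tnfsfm13 (7.19-fold higher) 8. Of the 394 higher genes 32, and of the 267 lower genes 9, were read at spots marked as locally bright on either array, whatever the direction.

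**Figure D1:**
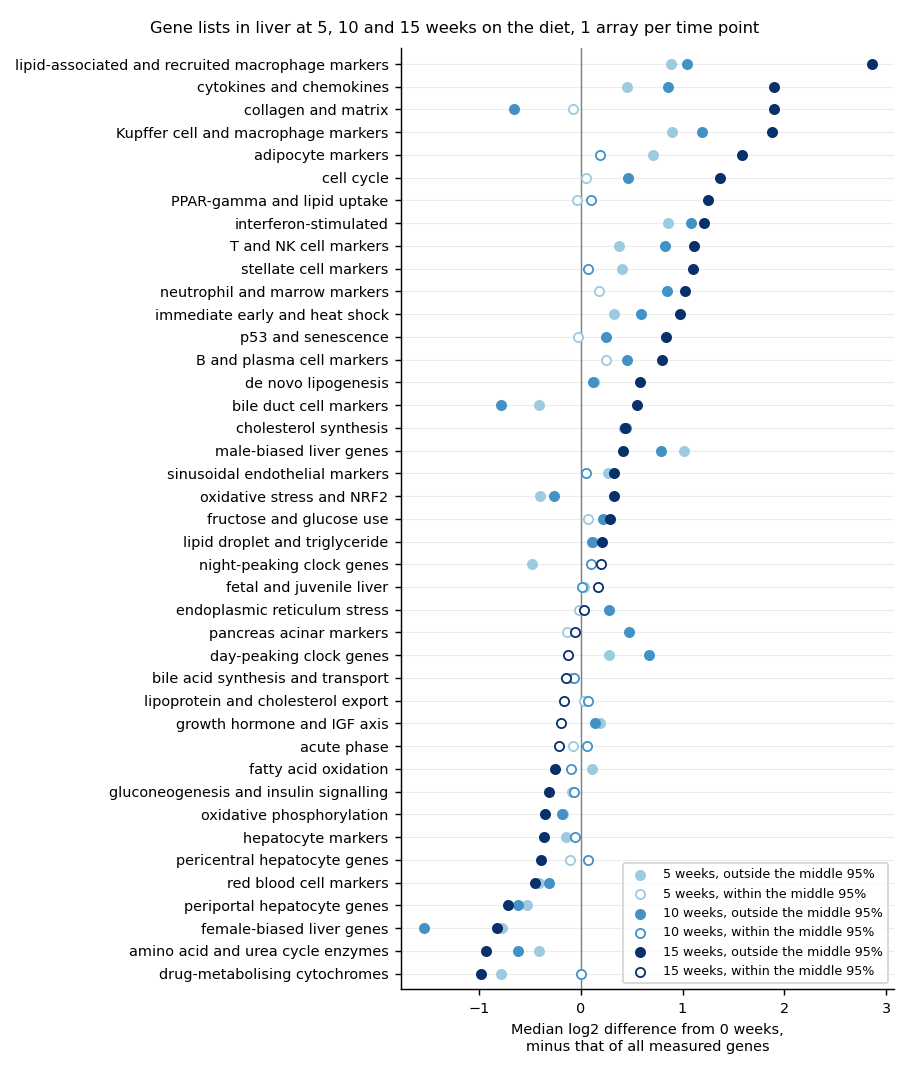
Median log2 difference from 0 weeks of the 41 gene lists at 5, 10 and 15 weeks, relative to the median of all measured genes, with filled points outside and open points within the middle 95% of random lists. Matrix genes stood at −0.08 at 5 weeks (0.14 and outside the random range on the upper side with the filter on all 4 arrays or the mean of each gene's probes), at −0.66 at 10 weeks and at 1.90 at 15 weeks, while macrophage markers stood at 0.89, 1.19 and 1.88.

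At 10 weeks against 0 weeks, Cfd (20.6-fold higher) and Hsd3b5 (17.7-fold higher) were again furthest above among genes with an official symbol outside the lowest-expressed part, followed by Cxcl1 (10.6-fold higher), while Serpina7, the thyroxine-binding globulin, of the lowest-expressed part at this comparison, was 12.7-fold higher. Car3 (7.42-fold higher), the adhesion receptor Adgrv1 (7.35-fold higher), the kinase Aatk (7.27-fold higher), the neutrophil calcium-binding protein S100a9 (5.47-fold higher) and the clock output factor Dbp (5.25-fold higher) were also among the 10 highest so ranked. Cyp2b10, a cytochrome induced by xenobiotics, was 227-fold lower. Smooth muscle actin Acta2 (19.3-fold lower), Krt19 (13.6-fold lower), Lgals2 (11.1-fold lower), Cyp2s1 (9.81-fold lower), Vsig2 (9.72-fold lower) and the membrane protein Prom1 (8.76-fold lower) were also among the lowest genes, together with B3galnt1 (17.5-fold lower) and Tfdp2 (12.7-fold lower), the spots with bright neighbours on the 0-week array. Of 17141 measured genes, 500 were at least 2-fold higher and 263 lower, and the share of higher genes was 65.5%, or 54.3% with scaling to the array median. Mpzl3 was 8.03-fold higher, had 10 of 44 neighbours bright on the 10-week array, and differed by −0.43 on the log2 scale with its other probe.

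Macrophage and lymphocyte markers stood above the median gene at 10 weeks. Of 22 macrophage markers, 15 were at least 2-fold higher and 7 within 2-fold (relative median 1.19), with Mpeg1 3.80-fold higher, Lyz2 2.95-fold higher and the signalling adaptor Tyrobp 2.65-fold higher. Markers of lipid-associated and recruited macrophages had 7 of 13 higher, 1 lower and 5 within 2-fold (1.04), with Cx3cr1 4.64-fold higher, Clec7a 3.33-fold higher and Trem2 3.11-fold higher. T and NK cell markers had 5 of 13 higher and 8 within 2-fold (0.83), among them Cd7 (2.70 on the log2 scale), the granzyme Gzma (4.52-fold higher) and Cd2 (2.47-fold higher). Interferon-stimulated genes had 14 of 24 higher and 10 within 2-fold (1.09), and cytokines and chemokines 6 of 13 higher and 7 within 2-fold (0.85), with Ccl2 4.58-fold higher and Cxcl9, an interferon-induced chemokine, 3.24-fold higher. All 5 medians lay outside the random range, while sinusoidal endothelial markers (0.05) and hepatocyte markers (−0.06) lay within it, with 0 of 17 and 1 of 17 members at least 2-fold different. The mean of the hepatocyte markers, −0.22, lay outside the range of random means (percentile 1.37).

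Some lipogenic and sterol genes were higher at 10 weeks. Fatty acid synthesis had 5 of 21 members at least 2-fold higher and 16 within 2-fold, among them the ligase Aacs (2.51-fold higher), Srebf1, the transcription factor that drives these genes (2.48-fold higher), and the stearoyl-CoA desaturase Scd1 (2.21-fold higher). Its relative median of 0.12 lay outside the random range, but within it at 0.025 with repeat-bearing probes left out, at 0.10 with the mean of each gene's probes, and with unmatched random lists (percentile 94.99). Cholesterol synthesis had 6 of 25 higher and 19 within 2-fold (0.44, outside), with Sqle 3.62-fold higher, the sterol transporter Stard4 2.38-fold higher and Cyp51 2.32-fold higher. Cyp7a1 was 4.35-fold higher and Cyp7b1 4.49-fold higher. Fatty acid oxidation genes lay within the random range (−0.09), with Fgf21 2.59-fold higher and the peroxisomal enzyme Ehhadh 3.27-fold lower. Adipocyte markers had 2 of 7 higher and 5 within 2-fold, with a median within the random range (0.19) and a mean of 1.01 outside it. Genes of PPAR-gamma and lipid uptake had 2 of 15 higher, 2 lower and 11 within 2-fold (0.10, within, but outside at percentile 98.49 with no background filter). Lipid droplet genes had 3 of 21 higher and 18 within 2-fold (0.11, outside, but within by the mean, with unmatched random lists and with normexp, at percentiles 96.81, 92.92 and 97.45).

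Matrix and bile duct genes stood apart as groups at 10 weeks, and 3 of 17 stellate cell markers were lower. Of 19 collagen and matrix genes, 5 were at least 2-fold lower and 14 within 2-fold, with a relative median of −0.66, outside the random range, and the fibrillar collagens Col1a1 and Col1a2 were 2.67-fold and 2.33-fold lower. Bile duct cell markers had 5 of 12 lower and 7 within 2-fold (−0.78, outside), with Krt19, the annexin Anxa13 (6.39-fold lower), Krt7 (3.37-fold lower) and the tight junction claudin Cldn7 (3.05-fold lower). Cldn7 stood at 0.01 with the mean of its probes. Stellate cell markers had a median within the random range (0.07) and a mean of −0.45 outside it, with 3 of 17 lower and 14 within 2-fold, and the 3 were the contractile or filament genes Acta2, Tagln (5.25-fold lower) and Des (4.27-fold lower).

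Sex-biased genes stood apart at 10 weeks too, with 6 of 15 male-biased genes at least 2-fold higher and 9 within 2-fold (0.79) and 7 of 11 female-biased genes lower and 4 within 2-fold (−1.54), both outside the random range. Sult1e1, the estrogen sulfotransferase, was 6.96-fold lower. Amino acid and urea cycle enzymes had 3 of 22 lower and 19 within 2-fold (−0.62, outside), with the argininosuccinate lyase Asl 2.80-fold lower and Cps1, the first enzyme of the urea cycle, 2.21-fold lower. Day-peaking clock genes had 3 of 11 higher, 1 lower and 7 within 2-fold (0.67, outside), with Dbp and Nr1d1, a nuclear receptor of the clock (2.46-fold higher). Drug-metabolising cytochromes had a median within the random range (0.00) and a mean of −0.86 outside it, with 3 of 14 lower and 11 within 2-fold, and the median lay outside too with no background filter (percentile 1.37).

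At 15 weeks against 0 weeks, the genes furthest above, among those with an official symbol outside the lowest-expressed part, were Cx3cr1 (31.8-fold higher), Serpina7 (30.9-fold higher), Nrg1, a growth factor of the ErbB receptors (29.8-fold higher), and Ccl2 (28.7-fold higher). Osbpl3, an oxysterol-binding protein relative (25.6-fold higher), Trem2 (23.2-fold higher), Adgrv1 (21.5-fold higher), Atf3, a stress-induced transcription factor (16.4-fold higher), and Itgax, the integrin CD11c (16.2-fold higher), were also among the 10 highest. Among the lowest were Cyp2b10 (19.4-fold lower), the smooth muscle genes Actg2 (14.3-fold lower) and Cnn1 (−3.40 on the log2 scale), the transporter Slc13a2 (13.2-fold lower), Lgals2 (13.2-fold lower), Smim38 (14.7-fold lower) and Eif4ebp3, a translation repressor (13.1-fold lower). Of 17560 measured genes, 1011 were at least 2-fold higher and 884 lower.

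The balance of higher and lower genes at 15 weeks depended on the scaling, the threshold and the filter. The share of higher genes was 53.4%, and it was 71.2% with the 75th percentile of detected probes, 67.4% with normexp and 86.5% with spike-in scaling. It turned the other way with a 1.5-fold threshold, with 1746 higher and 3251 lower, and with no background filter, with 2368 higher and 2973 lower. Against the median measured gene, 1424 genes were at least 2-fold higher and 486 lower.

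Macrophage markers stood well above the median gene at 15 weeks, with 18 of 22 at least 2-fold higher and 4 within 2-fold, or 20 higher against the median gene, at a relative median of 1.88. Lyz2 was 6.94-fold higher, Cd68 5.24-fold higher, Mpeg1 5.20-fold higher and Adgre1, the macrophage marker F4/80, 3.18-fold higher. Markers of lipid-associated and recruited macrophages had 11 of 13 higher and 2 within 2-fold (2.86), and cytokines and chemokines 10 of 13 higher and 3 within 2-fold, or 11 higher against the median gene (1.90), with Cxcl1 6.65-fold higher, Cxcl14 6.08-fold higher and Cxcl10, an interferon-induced chemokine, 4.17-fold higher. T and NK cell markers had 4 of 13 higher, 1 lower and 8 within 2-fold, or 8 higher and 0 lower against the median gene (1.11). B and plasma cell markers had 1 of 9 higher and 8 within 2-fold, or 2 higher against the median gene (0.80), and neutrophil markers 4 of 9 higher and 5 within 2-fold, or 5 higher against the median gene (1.03), with S100a9 5.30-fold higher. Interferon-stimulated genes had 11 of 24 higher and 13 within 2-fold, or 16 higher against the median gene (1.21), with Oas1a 6.13-fold higher and Oas2 4.73-fold higher. All 7 medians lay outside the random range, that of neutrophil markers not with no background filter (percentile 97.03). Sinusoidal endothelial markers had 0 of 17 at least 2-fold different (0.33, outside, but within by the mean, 0.09, and with the mean of each gene's probes, at 0.21). Hepatocyte markers had 4 of 17 lower and 13 within 2-fold, or 2 lower against the median gene (−0.36, outside, but within with normexp, at −0.05 and percentile 3.08).

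Collagen and matrix genes stood above the median gene at 15 weeks, with 14 of 21 at least 2-fold higher and 7 within 2-fold, or 17 higher against the median gene, at a relative median of 1.90, outside the random range. Col6a3 was 7.97-fold higher, Col3a1 4.80-fold higher, Col1a1 4.60-fold higher, all collagen chains, and the matrix glycoprotein Thbs1 4.76-fold higher. Stellate cell markers had 5 of 17 higher, 1 lower and 11 within 2-fold, or 9 higher against the median gene (1.10, outside), with Vim, the mesenchymal filament vimentin, 3.32-fold higher, the growth factor receptor Pdgfrb 3.32-fold higher and Acta2 3.24-fold lower. Bile duct cell markers stood at 0.55 with 2 of 13 higher, 2 lower and 9 within 2-fold, outside the random range by the median and within it by the mean (0.30), with the secreted phosphoprotein Spp1 6.11-fold higher and Krt19 3.95-fold lower. Cell cycle genes had 11 of 21 higher, 1 lower and 9 within 2-fold, or 12 higher against the median gene (1.36, outside), among them Cdc20, an activator of the anaphase complex (13.3-fold higher), the proliferation marker Mki67 (7.95-fold higher) and the cyclins Ccnd1 (5.63-fold higher) and Ccnb2 (5.51-fold higher).

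**Figure D2:**
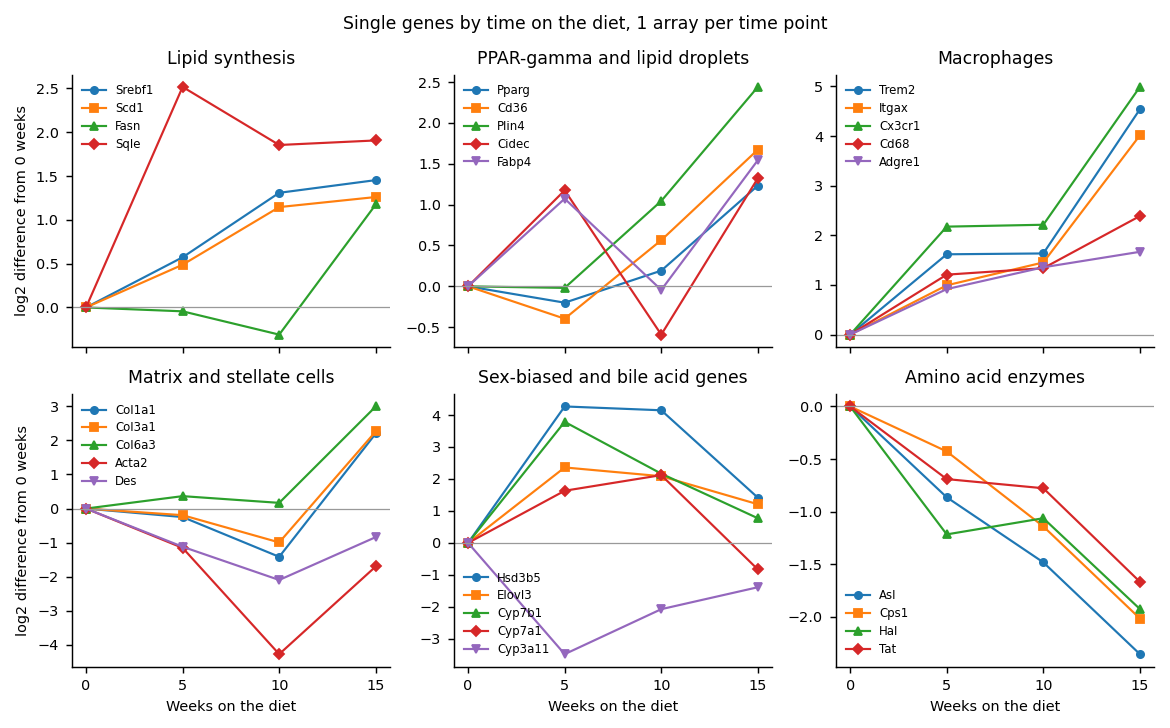
Log2 difference from 0 weeks at 5, 10 and 15 weeks, as scaled, for genes of lipid synthesis, lipid uptake and storage, macrophages, matrix and stellate cells, sex-biased or cytochrome genes and amino acid enzymes, with 1 array per point. Col1a1 stood at −1.42 at 10 weeks and 2.20 at 15 weeks, and Trem2 at 1.62, 1.64 and 4.54.

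Some genes of lipid uptake and storage were higher at 15 weeks. Of 15 genes of PPAR-gamma and lipid uptake, 7 were at least 2-fold higher, 1 lower and 7 within 2-fold, or 8 higher and 0 lower against the median gene, at a relative median of 1.25, outside the random range, with the droplet protein Plin4 5.43-fold higher, the fatty acid translocase Cd36 3.19-fold higher, Fabp4 2.92-fold higher and Mogat1, a monoacylglycerol acyltransferase, 2.52-fold higher. Pparg, the nuclear receptor itself, was 2.35-fold higher. Lipid droplet genes had 5 of 21 higher, 1 lower and 15 within 2-fold, or 5 higher and 0 lower against the median gene. Their median was −0.04 as scaled and 0.21 relative to the median gene, outside the random range, but within it at percentile 96.19 with unmatched random lists. Adipocyte markers, which share Fabp4 and Cidec with these lists, had 5 of 8 higher and 3 within 2-fold (1.59, outside), with Cfd 14.7-fold higher. Fatty acid synthesis had 7 of 21 higher and 14 within 2-fold (0.58, outside), including the desaturase Scd2 (2.89-fold higher), Srebf1 (2.74-fold higher) and Fasn (2.26-fold higher). Cholesterol synthesis had 4 of 25 higher and 21 within 2-fold, or 5 higher against the median gene (0.43, outside), with Sqle 3.75-fold higher.

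Amino acid and urea cycle enzymes stood below the median gene at 15 weeks, with 15 of 22 at least 2-fold lower and 7 within 2-fold, or 10 lower against the median gene, at a relative median of −0.93. Asl was 5.12-fold lower, Cps1 4.05-fold lower, Hal 3.80-fold lower and the tyrosine aminotransferase Tat 3.18-fold lower. Drug-metabolising cytochromes had 9 of 16 lower and 7 within 2-fold, or 7 lower against the median gene (−0.98), periportal genes 8 of 16 lower and 8 within 2-fold, or 6 lower against the median gene (−0.71), and pericentral genes 1 of 15 higher, 2 lower and 12 within 2-fold, or 2 higher and 1 lower against the median gene (−0.39). Oxidative phosphorylation stood at −0.35 with 0 of 29 members at least 2-fold different. All 5 medians lay outside the random range, as did that of female-biased genes (−0.82, 7 of 12 lower, 1 higher, 4 within 2-fold, or 5 lower and 1 higher against the median gene). Male-biased genes stood at 0.41, outside too, with 4 of 15 higher, 3 lower and 8 within 2-fold, or 5 higher and 1 lower against the median gene, and Hsd3b5 was 2.67-fold higher. Fatty acid oxidation genes stood at −0.25, with 2 of 30 higher, 6 lower and 22 within 2-fold, or 3 higher and 4 lower against the median gene, outside the random range. With quantile normalization this list stood at 0.06 and with normexp at 0.02, both within it and with 3 higher and 2 lower, and it also lay within with the filter on all 4 arrays (percentile 2.96) and with locally bright spots left out (3.12). The means of the oxidative phosphorylation, pericentral and oxidation lists (−0.46, −0.31 and −0.23) lay within the range of random means.

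Probes whose sequence holds a run of at least 5 TG units formed a group of their own at 15 weeks. Of 156 such measured probes, 123 were at least 2-fold lower and 0 higher, at a median of −1.63 relative to all probes, and they gave 123 of the 884 lower genes. The probe of Scn8a, a sodium channel gene (14.3-fold lower), was among them, with 8 TG units. Of 65 measured probes with at least 5 AC units, 25 were higher and 4 lower, at a relative median of 0.324. Probes with AC repeats read 20 of the 1011 higher and 4 of the 884 lower genes. Locally bright spots gave 40 of the 1011 higher and 38 of the 884 lower genes, among them Slc35e3 (16.4-fold higher) with 8 of 44 neighbours bright on the 15-week array, and B3galnt1 (13.3-fold lower) and Tfdp2 (19.2-fold lower), named above for their neighbours at 0 weeks. Of 988 spots marked as locally bright on the 15-week array, a shuffled array gives 344 by chance, against 0.95 of 323, 0.1 of 513 and 0.05 of 568 on the 0-, 5- and 10-week arrays. With repeat-bearing probes left out 1754 genes were at least 2-fold different, and with locally bright spots left out 1813, against 1895 in all.

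**Figure D3:**
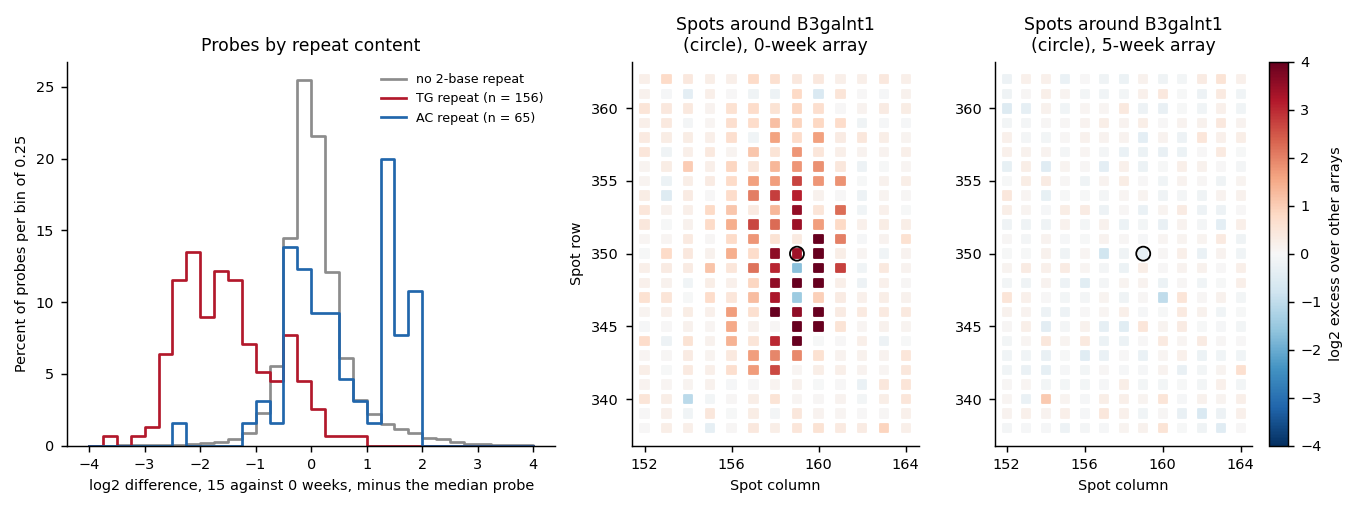
Histograms of the probe log2 difference between 15 and 0 weeks relative to the median probe, for probes without a repeat, with at least 5 TG units (156) and with at least 5 AC units (65), and maps of spot log2 excess over the other arrays around the B3galnt1 spot on the 0-week and 5-week arrays. TG probes centre on −1.63, and 27 of 44 neighbours of B3galnt1 are bright at 0 weeks against 0 at 5 weeks.

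Between 5 and 10 weeks fewer genes differed, with 163 of 17107 at least 2-fold higher and 194 lower at 10 weeks. Acta2 was 8.67-fold lower, Col1a1 2.25-fold lower, the asparagine synthetase Asns 4.49-fold lower, Cidec 3.40-fold lower and Cyp7b1 3.07-fold lower. Cyp3a11, Cyp3a16 and Cyp2a4 were 2.65-fold, 2.97-fold and 3.12-fold higher, and the 12 measured drug-metabolising cytochromes stood at 0.81 with 5 higher and 7 within 2-fold, outside the random range. The share of higher genes was 45.7%, or 29.0% with spike-in scaling, while higher genes were the larger part with a 1.5-fold threshold (837 higher, 693 lower) and with no background filter (1645 and 1477).

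Between 10 and 15 weeks, matrix, macrophage and cell cycle genes stood higher and several clock and male-biased genes lower. Of 20 collagen and matrix genes, 19 were at least 2-fold higher and 1 within 2-fold, at a relative median of 2.16. Timp1, an inhibitor of matrix proteases, was 16.2-fold higher, Col1a1 12.3-fold higher and Col3a1 9.55-fold higher. Markers of lipid-associated and recruited macrophages had 10 of 13 higher and 3 within 2-fold, or 11 higher against the median gene (2.45), with Trem2 7.48-fold higher, cell cycle genes 11 of 22 higher and 11 within 2-fold, or 13 higher so counted (1.30), with the kinase Plk1 4.52-fold higher, bile duct markers 8 of 13 higher and 5 within 2-fold, or 9 higher so counted (1.73), and genes of PPAR-gamma and lipid uptake 9 of 16 higher and 7 within 2-fold (1.26), with Cidea, a droplet protein, 23.7-fold higher and the lipoprotein lipase Lpl 5.58-fold higher. Male-biased genes had 8 of 16 lower and 8 within 2-fold, or 5 lower against the median gene (−0.75), with Hsd3b5 6.65-fold lower, and day-peaking clock genes 4 of 11 lower and 7 within 2-fold, or 3 lower so counted (−0.62), with Usp2 4.67-fold lower and Dbp −1.96 on the log2 scale. All 7 medians lay outside the random range. Of 17489 measured genes, 691 were higher and 710 lower, and 118 of the lower genes were read by TG-repeat probes. The share of higher genes was 49.3%, and 68.1% with the array median, 69.8% with the 75th percentile of detected probes, 59.7% with quantile normalization, 65.2% with normexp and 90.9% with spike-in scaling. Lower genes were the larger part with a 1.5-fold threshold (1439 higher, 2717 lower) and with no background filter (1944 and 3305), and no direction of the balance held under all settings.

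Genes at least 2-fold different from 0 weeks in the same direction at all 3 times numbered 145 higher and 79 lower, of 16684 measured on all 4 arrays, or 184 and 48 with spike-in scaling. Lower genes were the larger part with a 3-fold threshold (16 higher, 23 lower) and with no background filter (403 and 599). Among the 10 highest by their smallest difference, not yet named, were Nat8, an acetyltransferase (at 5 weeks 5.61-fold higher), Gdf15, a stress-induced cytokine (4.17-fold higher), and Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1 (4.58-fold higher). Among the lowest were Akr1b7, an aldo-keto reductase (9.32-fold lower), and Myo1a, a brush border myosin (4.52-fold lower). The 3 comparisons share the 0-week array. With the 5-, 10- or 15-week array as the shared one, the counts were 70, 55 and 565, against 224 for the 0-week array, and the mean over the 4 arrays was 228.5.

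The genes higher at 5 and at 10 weeks overlapped in 208, where independent lists give 10.6 and arrays shuffled within each gene 168. Of the lower genes 122 were in both, against 3.41 and 187. Over genes, which are not independent replicates, the differences at 5 and 10 weeks had a correlation of 0.66 against 0.496 shuffled and a covariance of 0.129 against 0.141, those at 5 and 15 weeks a covariance of 0.145 against 0.146, and those at 10 and 15 weeks 0.169 against 0.14. The differences at 10 and 15 weeks shared 308 higher genes (165 shuffled) and 126 lower (184 shuffled). Comparisons without a shared array overlapped less. For 5 against 0 and 15 against 10 weeks these were 54 higher and 32 lower genes (56 and 57 shuffled). For 10 against 5 and 15 against 0 weeks they were 44 and 29 (45 and 41 shuffled), so by these counts neither pair overlapped beyond the shuffled arrays. The correlations over genes of these pairs, 0.0662 and 0.0988, were small and above the shuffled 0.0157 and −0.0204. All shuffled values come from a single shuffle. With 1 array at 0 weeks the shared control could not be split, and part of the overlaps may come from it.

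Genes ordered in time, higher at every step and at least 2-fold from 0 to 15 weeks, numbered 451, the largest of the 24 orders of the arrays, and 322 were lower at every step, the next largest, against a mean of 114.8 over orders. The 0- and 15-week arrays differed in the most genes (1895), so orders that end in them rank high in part for that reason. With 5 and 10 weeks swapped, 216 genes were ordered upward and 224 downward. In the order of time, the split of higher and lower genes depended on the scaling of the arrays, with 567 higher and 176 lower with the 75th percentile of detected probes, 514 and 224 with quantile normalization, 352 and 124 with normexp and 651 and 93 with spike-in scaling. The higher genes were the largest order under each of these, while the lower genes ranked 5, 3, 3 and 8, and with spike-in scaling another order held 617. Genes ordered downward were the larger part with a 1.5-fold threshold (617 higher, 1036 lower) and with no background filter (861 and 1033). With repeat-bearing probes left out 437 were higher and 246 lower, so part of the 322 was read by such probes. Serpina7 (2.24, 3.66 and 4.95 on the log2 scale) and Adgrv1 (2.24, 2.88 and 4.42) were ordered upward, and Lgals2 (−2.65, −3.48 and −3.72) downward.

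Some genes were well above background at 1 of the times compared and not at the other, which gives a bound. At 5, 10 and 15 weeks 229, 268 and 345 genes not well above background at 0 weeks were at least 2-fold higher by this bound. At the same times 191, 248 and 330 genes above background at 0 weeks were at least 2-fold lower. With locally bright spots left out, 159, 207 and 307 were higher and 139, 191 and 267 lower. The 345 higher and 330 lower at 15 weeks became 430 and 229 with the 75th percentile of detected probes and 611 and 158 with spike-in scaling, and with normexp the counts were 41 and 52 at 5 weeks and 53 and 74 at 10 weeks. Lower genes were also the larger part at 5 weeks with the array median (203 higher, 206 lower) and a 3-fold threshold (90 higher of 197), and at 10 weeks with the array median (227 and 282), quantile normalization (250 and 277), spike-in scaling (245 and 268) and a 3-fold threshold (129 and 147). Cidea was at least 14.3-fold higher at 5 weeks, at least 13.2-fold higher at 10 weeks and at least 312-fold higher at 15 weeks, and Timp1 at least 44.6-fold higher at 15 weeks. Cyp2b10 was at least 1059-fold lower at 5 weeks. Tnf, an inflammatory cytokine, was at least 2.41-fold higher at 15 weeks. Chosen after their values were seen, Gpnmb, a macrophage glycoprotein, was at least 26.1-fold higher and Ccl7, a monocyte chemokine, at least 12.6-fold higher at 15 weeks, Moxd1, a male-biased monooxygenase, at least 209-fold higher at 5 weeks, and Reg1, a pancreatic stone protein gene, at least 48.6-fold lower at 15 weeks.

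The probes behind the most named genes lie, in build mm9, on chromosome 11 at 94813115 to 94813174 for Col1a1, on chromosome 17 at 48491537 to 48491596 for Trem2, on chromosome 7 at 26711522 to 26711581 for Cyp2b10, on chromosome 3 at 98422576 to 98422635 for Hsd3b5, and on chromosome 15 at 59162688 to 59162747 for Sqle. Those of Ccl2, Cps1 and Cfd lie on chromosome 11 at 81850650 to 81850709, chromosome 1 at 67276029 to 67276088 and chromosome 10 at 79355302 to 79355361. The exon and untranslated region at each probe were not analysed here, since no annotation of that build was used.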

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

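All tests weighed here were chosen only after the result was seen, except that of the other probes of genes with a TG repeat, whose prediction was set down before its result. Differences of direction between time points were not tested, since each time point has 1 array.

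Probes with at least 5 TG units were lower at 15 weeks as a group, by a median of −1.63 relative to all probes, with 123 of 156 at least 2-fold lower. The other probes of the same 46 genes, without a repeat, had a relative median of 0.135, where the repeat probes of those genes had −1.11, so the lower signal may come from the repeat and not from the genes. Weaker binding of every simple repeat on the 15-week array is argued against by the probes with an AC repeat, whose relative median was 0.324 (SD over probes 0.939). Probes with at least 5 AG units stood at 0.156 (32 probes), and those with at least 5 TC units went the other way, at −0.157 (38 probes). Leaving out repeat probes gave 1754 in place of 1895 genes at least 2-fold different. At 10 weeks TG probes stood at −0.325 and AC probes at 0.304, so shifts of repeat probes were not confined to the 15-week array. No biological explanation was tested, and what lowered the TG signal stays open.

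Spots at least 4-fold brighter on 1 array than on the others lay side by side. Of 468 such spots, 50.6% had another such spot close by, against 3.12% with random placement. By array these shares were 38.4%, 83.7%, 75.8% and 34.9% at 0, 5, 10 and 15 weeks. The neighbourhood here was smaller than the one that marks spots, and neighbours had to be at least 4-fold brighter. The bright neighbours below follow the 2-fold rule given for marked spots. A set of 136 probes with at least 5 bright neighbours was taken, each, like the 1173 below, itself at least 2-fold brighter than on the other arrays. Their excess was 2.80 on the log2 scale, in part through this choice, and does not describe all marked spots. Other probes of the same genes on the same array had 0.135, so local defects of single arrays are a candidate cause. At 1173 bright probes without such neighbours the excess was 1.41 and that of other probes 0.705, and on the 15-week array, where 344 of 988 marks arise in a shuffled array, the values at 46 marked probes were 2.25 and 0.156. That the other probes at marked spots stood lower than those at unmarked ones argues against genes high at a single time point as the whole source of the clusters. B3galnt1 and Tfdp2, lower at all 3 times, and Tmem159, Slc25a48 and Prickle3, higher at 5 weeks, were read at such spots.

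Macrophage markers, markers of lipid-associated macrophages, matrix genes and cell cycle genes stood together above the median gene at 15 weeks, at relative medians from 1.36 to 2.86. Scaling of the 15-week array as the whole cause is argued against by quantile and normexp scaling, under which the lowest relative median of the 4 lists was 0.641 and still outside the random range. A lower share of hepatocytes as the whole cause was weighed against 1 other cell type, sinusoidal endothelium. The lower quartile of macrophage markers was 1.513, and the upper quartile of sinusoidal endothelial markers was 0.478, so these did not move alike. Upper quartiles of bile duct (0.788), B cell (0.943) and T and NK cell markers (1.274) also lay below 1.513. Those of stellate cell (1.525), adipocyte (2.023) and neutrophil markers (2.657) lay above it. An equal rise of all other cells is thus argued against for macrophage markers, and a rise shared with the latter cells is not. The lower quartiles of lipid-associated macrophage markers (1.921) and matrix genes (1.211) lay above 0.478 too, that of matrix genes below the 1.274 of T and NK cell markers. That of cell cycle genes (0.136) did not, so for them a lower share of hepatocytes stays open. Longer feeding may have raised these groups, and so could age, which moved with it. The time on the diet cannot be told apart from the animal or pool on the array, because there is 1 array at 15 weeks.

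The following stood on opposite sides of 0 weeks at different times, and these differences were not tested. Bile duct cell markers stood at −0.41 at 5 weeks and −0.78 at 10 weeks, and at 0.55 at 15 weeks. Their means at 5 and 15 weeks, −0.25 and 0.30, lay within the range of random means. Collagen and matrix genes stood at −0.66 at 10 weeks and 1.90 at 15 weeks, and Col1a1 at −1.42 and 2.20. Fatty acid oxidation genes stood at 0.11 at 5 weeks and −0.25 at 15 weeks. The change of side was lost with quantile normalization and normexp, which gave 0.06 and 0.02 at 15 weeks. Genes of oxidative stress and NRF2 stood at −0.40 at 5 weeks, −0.27 at 10 weeks and 0.32 at 15 weeks. H19, an imprinted non-coding RNA of fetal liver, stood at −1.02 at 10 weeks and 2.30 at 15 weeks.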

How the results depend on the processing

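Spike-in scaling, leaving out repeat probes, leaving out locally bright spots and keeping the duplicate clock entry were chosen only after the data were seen. No paired analysis was possible because each time point has 1 array. Of the values of 16 counts under all alternatives, 141 stayed within 1.5 times and 41 moved further. These are totals of higher and lower genes and so have no sign, while the larger part changed sides under some alternatives. Of the values of 123 list results, 1731 kept their side of the random range and sign, 109 moved and 2 reversed. Of those of 560 results of named genes, 6457 were called as before, 204 moved and 3 reversed. Signal over background limits what is read, since a gene not well above background on an array has only a bound there. The cause of no difference below was tested, except that a lower or higher threshold and the absence of a filter change counts by construction.

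With normexp and quantile normalization 276, 341 and 979 genes were at least 2-fold different from 0 weeks at 5, 10 and 15 weeks, 147 between 5 and 10 weeks and 615 between 10 and 15 weeks. Under it 90 went the same way at all 3 times, 476 were ordered in time, and 93, 127 and 125 were above background at 1 of both times and at least 2-fold different by bound, of which 41, 53 and 74 were higher than at 0 weeks and 52, 74 and 51 lower. With no background filter the counts were 3456, 3787, 5341, 3122 and 5249, with 1002 the same way and 1894 ordered, and no bound could be given. Among these the higher and lower genes were 2368 and 2973 at 15 weeks, 1645 and 1477 between 5 and 10 weeks, 403 and 599 the same way and 861 and 1033 ordered. With a 1.5-fold threshold they were 2065, 2079, 4997, 1530 and 4156, with 714 the same way, 1653 ordered and 852, 1021 and 1039 by bound, and the higher and lower genes were 1746 and 3251 at 15 weeks, 837 and 693 between 5 and 10 weeks, 1439 and 2717 between 10 and 15 weeks and 617 and 1036 ordered. With a 3-fold threshold they were 187, 215, 719, 102 and 427, with 39 the same way (16 higher, 23 lower), 368 ordered and 197, 276 and 302 by bound. Spike-in scaling gave 2149 between 10 and 15 weeks.

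Fatty acid oxidation genes at 15 weeks stood at 0.06 (0.057) with quantile normalization and 0.02 (0.022) with normexp. With the mean of its probes Cldn7 stood at 0.22 (0.217) at 5 weeks and 0.01 (0.007) at 10 weeks. With locally bright spots left out Mpzl3 stood at −0.43 at 10 weeks.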

Other observations

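No test of a hypothesis is reported here, and spots with bright neighbours were left out of a list only after the data were seen. Immediate early and heat shock genes stood above the median gene at all 3 times, at 0.33, 0.59 and 0.97, all outside the random range, with 3 of 17, 6 of 19 and 8 of 18 at least 2-fold higher and 0 lower, or 9 higher at 15 weeks against the median gene. At 5 weeks they included Egr1 (3.75-fold higher) and Hspa1a, an inducible heat shock protein (2.91-fold higher), at 10 weeks Fos (7.17-fold higher) and at 15 weeks Klf6 (5.48-fold higher). Genes of p53 and senescence stood at −0.02, 0.24 and 0.84, the latter pair outside, with 1 higher and 2 lower of 16 at 5 weeks, 3 higher and 2 lower at 10 weeks, and 5 higher and 0 lower at 15 weeks, or 8 higher against the median gene. Gdf15 was 13.6-fold higher at 15 weeks, Phlda3 6.29-fold higher, and Cdkn1a, the cell cycle inhibitor p21, was 3.88-fold lower at 10 weeks and stood at 0.24 at 15 weeks. Endoplasmic reticulum stress genes stood at −0.02, 0.27 and 0.03, outside at 10 weeks, when 3 of 24 were higher, 1 lower and 20 within 2-fold, and by the mean also at 15 weeks (0.23). The medians of acute phase genes lay within the random range (−0.08, 0.07 and −0.21). The list lay outside at 5 weeks with normexp (percentile 1.08) and the mean of each gene's probes (0.79), at 10 weeks by the mean (99.99), with quantile normalization (98.33) and with the mean of probes (99.48), and at 15 weeks with unmatched random lists (1.09). This list had 5 of 26 higher, 6 lower and 15 within 2-fold at 15 weeks, or 5 higher and 3 lower against the median gene and 5 higher and 1 lower with quantile normalization or normexp, with Saa1 6.92-fold higher at 5 weeks and Lcn2, the lipocalin of activated neutrophils and hepatocytes, 2.96-fold higher at 15 weeks.

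Several clock genes stood nearer to 0 weeks at 15 weeks than at 5 and 10 weeks. Day-peaking genes stood at 0.28 and 0.67 at 5 and 10 weeks, outside the random range (at 5 weeks within it, at 0.12, with the mean of each gene's probes), and at −0.13 at 15 weeks, within it, and Dbp stood at 2.02, 2.39 and 0.43 on the log2 scale. Arntl, which peaks opposite to Dbp, stood at −1.36, −1.64 and −0.42, and the 5 measured night-peaking genes at −0.48 (outside, but within at percentile 9.48 with no background filter), 0.10 and 0.20. The hour of sampling is not given in the sources used here. Genes of the growth hormone and IGF axis stood at 0.19 and 0.14, outside, and −0.20 at 15 weeks, within, with Socs2 2.99-fold higher and Cish 2.47-fold higher at 5 weeks, both inhibitors of cytokine signalling, and Lepr, the leptin receptor, 3.78-fold lower at 15 weeks. The list at 10 weeks lay within the range with locally bright spots left out (0.06), by the mean (percentile 92.98) and with unmatched random lists (94.87).

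Genes of fructose and glucose use stood at 0.08, 0.22 and 0.29, outside from 10 weeks on and by the mean also at 5 weeks (0.16), with G6pdx, the entry enzyme of the pentose phosphate pathway, 2.29-fold higher and the fructose transporter Slc2a5 2.26-fold lower at 15 weeks. Gluconeogenesis and insulin signalling genes stood at −0.08, −0.07 and −0.31, outside at 15 weeks, but within there by the mean (−0.43) and with the mean of each gene's probes (−0.25). At 5 weeks the mean of probes (percentile 1.84) and at 10 weeks the mean of the list (1.72) put them outside. G6pc, the glucose-6-phosphatase, was 2.07-fold lower at 15 weeks. Lipoprotein and cholesterol export genes lay within the random range by the median (0.03, 0.07 and −0.16) and outside by the mean at 5 and 10 weeks (percentiles 98.2 and 98.7), with the phospholipid transfer protein Pltp 2.96-fold higher at 10 weeks and Abcg1, a sterol exporter, 2.48-fold higher at 15 weeks. Fetal and juvenile liver genes also had medians within it (0.03, 0.02 and 0.17), but at 15 weeks lay outside by the mean (0.54), with the filter on all 4 arrays (percentile 97.81), the mean of probes (98.5) and locally bright spots left out (97.69), with H19 4.92-fold higher and Ly6d 4.91-fold higher at 15 weeks. Lists whose mean and median differed in sign were PPAR-gamma and lipid uptake (means 0.16 and −0.04), bile acid synthesis (0.08 and 0.05) and fetal liver (−0.07 and −0.14) at 5 and 10 weeks, collagen and matrix (0.02), endoplasmic reticulum stress (0.05) and p53 (0.02) at 5 weeks, and night-peaking (−0.07) and pericentral genes (−0.06) at 10 weeks, besides those named above, and lipoprotein genes (0.01) at 15 weeks.

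Markers of further cell types that a liver sample can hold were read in the same way. Red blood cell markers stood at −0.41, −0.32 and −0.45, outside the random range, with 0, 0 and 1 of 9 at least 2-fold lower, the last being Klf1 (3.48-fold lower). They lay within it at 10 weeks by the mean (−0.27), and at 15 weeks with quantile normalization (−0.21), normexp (percentile 3.0) and no background filter (10.11). Pancreas acinar markers stood at −0.14, 0.48 and −0.06, outside at 10 weeks, where the call rests on 5 genes and is lost by the mean (0.02) and with normexp (0.19), with Ctrb1, a chymotrypsinogen, 4.96-fold lower at 15 weeks and Cela1 3.47-fold higher. Stellate cell markers stood at 0.41 at 5 weeks, outside by the median and within by the mean (0.09), with 0 of 17 higher, 3 lower and 14 within 2-fold. At 5 weeks T and NK cell markers stood at 0.37, outside, with 1 of 13 higher and 12 within 2-fold. B and plasma cell markers stood at 0.25 at 5 weeks, within the range but outside with unmatched random lists and with no background filter (percentiles 98.14 and 97.81), and at 0.45 at 10 weeks, outside but within with normexp (96.41). Neutrophil markers stood at 0.17 at 5 weeks, within by the median and outside by the mean (0.58), and at 0.85 at 10 weeks, outside, with 3 higher and 0 lower both times. Among contractile and epithelial genes highest at 0 weeks, Acta2 stood at −1.15, −4.27 and −1.70 and Krt19 at −2.34, −3.77 and −1.98 at 5, 10 and 15 weeks.

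Of the lists described above at some times, the remaining times stood as follows. Cell cycle genes stood at 0.05 at 5 weeks, within the random range, and at 0.46 at 10 weeks, outside, with 4 of 19 higher and 15 within 2-fold. Oxidative phosphorylation stood at −0.17 and −0.18 at 5 and 10 weeks, outside, with 0 of 29 members at least 2-fold different both times. Genes of oxidative stress and NRF2 stood at −0.27 and 0.32 at 10 and 15 weeks, outside on opposite sides, and periportal genes at −0.62 at 10 weeks, outside, with 4 of 16 lower. Pericentral genes stood at −0.11 and 0.07 at 5 and 10 weeks, within, but at 5 weeks outside by the mean (−0.21) and with repeat-bearing probes left out (percentile 1.94). Bile acid genes stood at −0.07 and −0.14 at 10 and 15 weeks, within, but at 15 weeks outside with the mean of each gene's probes (−0.32).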
